A study of Mus musculus with 9 samples.

How the data were processed

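Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adaptors into open DNA, in dendritic cells grown from C57Bl/6 mouse bone marrow. Per the labels, cultures ran for 9 days in 20 ng/mL GM-CSF, the cytokine that drives marrow cells towards this cell type. Retrovirus was added on day 2, and cells carrying both the human CD8 reporter of the vector and CD11c were sorted. There were 9 libraries: 2 for each of 4 vectors and 1 input. The vectors were the mi8 control and its partner that overexpresses Pcgf6 (OE), and the LMP8 control and its partner that expresses a hairpin RNA against Pcgf6 (HP109).

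The authors deposited 1 peak list per vector, and the labels attach it to both libraries of that vector, so the 4 lists have no replicate spread. For that reason no test between conditions was run, and no standard deviation or sample number stands beside a value. Reads were aligned with BWA, handled with Picard and turned into peaks with MACS2 on build mm10, per the submitters' processing notes. Per the labels, each list was called against the single input library, which came with the mi8 vector, and the list names carry the word downsample. Versions, thresholds, read shifting, the depth aimed at and the way the 2 libraries were pooled are not given in the sources used here.

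The score column deposited by the authors is 10 times the −log10 q of the peak as a whole number. The fold column deposited by the authors is the ratio of the read pileup at the summit to the local background that the peak caller set from the input. The −log10 p and −log10 q columns deposited by the authors state how far the summit lies above that background. The fold and −log10 q of a peak are the authors' own values throughout, and they serve to describe, rank or filter peaks within 1 list. Peaks with several summits in 1 interval were collapsed to the summit with the highest −log10 q, and peaks on chromosomes 1 to 19, X and Y were kept.

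Because read totals are not given in the lists, the summit pileup and its background were recovered from the fold and the −log10 p, taking the fold as (pileup + 1) over (background + 1) and p as a Poisson tail. A whole-number pileup matched the printed −log10 p within 0.001 for 100% of the peaks in each of the 4 lists. The smallest background in a list and the steps between backgrounds, which follow the input scaled to the depth of the list, gave the relative depths. They come to 14.1 reads per kb of genome-wide background for HP109, 14.2 for LMP8, 19.4 for OE and 19.5 for mi8. Depth was therefore matched within each pair of vector and control and was 1.37 times as high in mi8 as in LMP8.

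Peak lists were compared by overlap of at least 1 bp. A peak of 1 list that overlapped no peak of the other is called absent from the other, and a Jaccard index gives shared over covered base pairs. Shares of peaks carry exact (Clopper-Pearson) 95% intervals, which cover counting error alone and not the spread between cultures. Regions were made by merging the peaks of the 4 lists. For the question whether the 2 Pcgf6 vectors act on the same regions in opposite ways, mi8 regions present in HP109 and absent from LMP8 were set against mi8 regions present in LMP8 and absent from HP109, matched in 20 bins of mi8 −log10 q.

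Gene positions came from a RefSeq table of the GRCm38.p6 assembly, the assembly of mm10, with 21887 protein-coding genes and neither strand nor exons. The transcription start site of the plan was therefore replaced by either end of the gene, with 1000 bp on each side, and regions were assigned to the nearest gene span within 100 kb. Classes of exon and intron, the account of Pcgf6 exon by exon and the search for sequence motifs needed exon positions or a genome sequence and were not run.

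Before the data were examined, the comparisons, the alternatives, the naming rule and 18 gene lists were fixed; later choices are named where they occur. The lists held 360 entries, of which 358 were found, naming 355 different genes; Mx1 and Mx2 were not found as protein-coding genes. The lists were genes of the PRC1.6 complex and Pcgf paralogs, germline genes, antigen presentation, costimulation and maturation, inflammatory cytokines and chemokines, NF-kB and Toll-like receptor signalling, interferon-stimulated genes, dendritic cell lineage factors, glycolysis and HIF, oxidative phosphorylation, cell cycle, developmental Polycomb targets and ubiquitous promoters, with markers of macrophages, of granulocytes and mast cells, of lymphoid and plasmacytoid cells, of erythroid cells and megakaryocytes, and of stroma. For each list the net share is the regions in the first peak list alone minus those in the second alone, as a percentage of all its regions in either. Its percentile was taken among 10000 random gene lists of the same size and similar numbers of regions per gene, and a list outside the central 95% is called outside. The percentile ranks genes within these libraries and is not a test between conditions. The random lists were not matched on peak strength.

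Genes were named by rule: Pcgf6 in every list; up to 25 members of the fixed lists with a peak at a gene end in 1 peak list and none in the other; the 10 gene ends with the highest −log10 q in 1 list and none in the other, per direction; the 10 gene ends opposed in both arms; and the 5 strongest absent intervals per direction. Most of the gene ends that ranked highest, in 1 arm or opposed in both, turned out to have a peak of the other list overlapping just outside the window. It was 10 of 10 for HP109 over LMP8, 10 of 10 for mi8 over OE and 8 of 10 for LMP8 over HP109, but 4 of 10 for OE over mi8. After this was seen, a check was added that removes such genes, and the gene ends named from these rankings are those left after it. Some results that this rule selects are not reported here. The fixed-list genes named for the comparisons of each vector with its control were not affected. Genes ranked by the number of absent peaks inside the gene beyond the share expected from the whole list were also added after the data were examined.

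Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The pileup recovery, the overlap, the gene list percentile and the matched comparison of opposed regions were tested on simulated data, and the other steps were not. The recovery returned 99.3% of 2901 simulated pileups, and the overlap step found 100% of the added and dropped peaks in simulations of each comparison. With 21887 genes, 100 of 100 planted gene lists and 4 of 100 unchanged lists fell outside the central 95%. The matched comparison of 60000 simulated regions gave 15.2 points where 15 were planted and −0.478 where none was planted.

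Alternatives fixed beforehand were a −log10 q of at least 5 or 10, equal numbers of peaks per list, 50% coverage as the overlap, a −log10 q of at least 10 in 1 list with no peak in the other, windows of 250 bp around the summit, no matching, a 20 kb limit for the nearest gene, and gene-end windows of 500 or 2500 bp. The alternatives added after seeing the data were thinning a list to the depth of another, the other control as the comparison, and the overlap check of named genes. The input library enters through the peak calls alone.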

Results

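Open chromatin was compared between bone marrow dendritic cells that carried a Pcgf6 vector and cells with the matching control vector. Pcgf6 is a Polycomb-group protein and the defining subunit of the repressive complex PRC1.6, and the series asks how raising or lowering it shapes dendritic cell activation. Each of the 4 vectors had 2 libraries behind 1 peak list. The lists held 170103 peaks for the knockdown HP109, 140735 for its control LMP8, 111510 for the overexpression OE and 170976 for its control mi8. They covered 51.2, 45.0, 35.3 and 55.9 Mb, with median widths of 219, 230, 228 and 236 bp in that order. The median fold over the input background was 8.07, 7.02, 7.33 and 7.22, and the lowest −log10 q in a list was at most 1.34. Of 194735 merged regions, 91658 (47.1%) were present in all 4 lists.

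At Pcgf6 itself (chromosome 19, 47033617 to 47050939, mm10), every list had peaks at both ends of the gene. In OE they spanned 47033722 to 47034683, with fold 11.7 and −log10 q 27.7, and 47050283 to 47050891, with fold 18.7 and −log10 q 55.7. In mi8 the strongest peaks at these ends had a −log10 q of 3.36 and 33.3, in HP109 16.5 and 18.7, and in LMP8 9.62 and 10.3. A peak inside the gene at 47035004 to 47035248 in mi8, with −log10 q 17.9, had a counterpart in HP109 and LMP8 and none in OE. Reads from a transduced Pcgf6 cDNA can map to exons of the gene, which are not annotated here, and a hairpin RNA acts on the transcript, so the peaks verify neither vector.

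**Figure D1:**
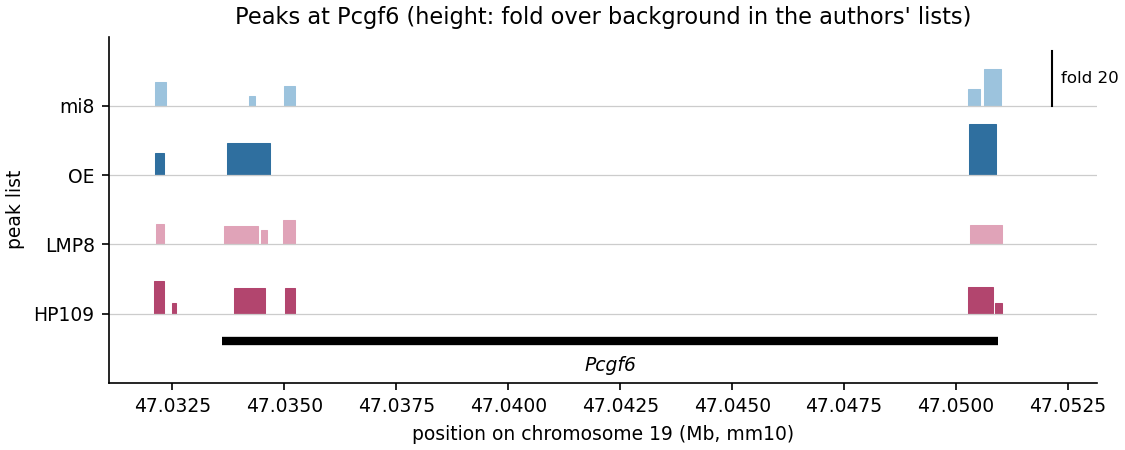
Peaks at Pcgf6 on chromosome 19 (position in mm10) in the 4 lists, 1 list per track, with bar height as the fold of each peak in the authors' list (scale bar, fold 20) and the gene as a black bar. OE has peaks at both ends of the gene and none at 47035004 to 47035248, where mi8, LMP8 and HP109 have one.

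The overexpression vector was compared with mi8 to see which sites accompany added Pcgf6. Among the mi8 peaks absent from OE were gene-end peaks of Il27, a cytokine of activated dendritic cells (−log10 q 24.0), Ciita, the master activator of MHC class II genes (16.9), the T cell attracting chemokines Cxcl9 (11.5) and Ccl5 (11.3), Il12a, a subunit of interleukin 12 (7.68), Ifnb1, which encodes interferon beta (8.41), and Ccr7, the receptor that guides mature dendritic cells to lymph nodes (4.76). HP109 and LMP8 both had an end peak at Il27, Ciita, Cxcl9, Il12a and Ifnb1, but neither had one at Ccl5 or Ccr7, whose peak was in mi8 alone. S100a9 (23.9), Ctsg (13.5) and Ngp (10.7), genes of granulocytes, and the B cell gene Ms4a1 (18.8) also had an end peak in mi8 and none in OE. Before the overlap check, 1481 of all 21887 genes (6.77%) were in this state, a share that the fixed lists, with 21 of 355 genes, did not exceed. In contrast, the gene body of Hif1a, the transcription factor of the hypoxia and glycolysis response, held 30 peaks in OE against 14 in mi8, 15 in HP109 and 11 in LMP8. In all, 68703 mi8 peaks (40.2%, interval 39.95 to 40.4) were absent from OE, and 5091 OE peaks (4.57%, interval 4.44 to 4.69) were absent from mi8. The mi8-only peaks outnumbered the OE-only peaks on 21 of 21 chromosomes. Between the 2 controls the longer list led on 21 of 21 too, so this count does not mark a Pcgf6 vector.

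Of the fixed lists, 21 genes had an end peak in mi8 and none in OE, and none had the reverse. HP109 and LMP8 both had an end peak at 12 of the 21 and neither had one at 4, Ccl5, Ccr7, Pax3 and Cdh5. Besides those above they included Foxa2 (11.8), Hbb-bs (7.76), Cd70 (6.61), Itga2b (6.61), Pdgfra (5.99), Kit (5.58), Pax3 (4.92), Ywhaz (3.69) and Cdh5 (2.64). With windows of 500 and 2500 bp, 14 and 16 of the 21 kept this state. Over all 21887 genes, 1412 had an end peak in mi8 and no counterpart in OE, and 37 the reverse. The strongest of the 1412 were Rnase6, an antimicrobial ribonuclease (63.9), Mlf1 (50.1), Gm8369 (48.1), Zfp2 (41.4), Gm40011 (38.9), the monocyte chemokine gene Ccl7 (36.8), Dlx4 (36.6), Lect2 (35.3), the interferon-induced gene Ifi44 (33.3) and Rims3 (33.1). The strongest of the 37 were 1700015G11Rik (20.5), Atad1 (13.9), Olfr1330 (9.92), Olfr974 (8.75), Lrp2bp (8.63) and Pik3ip1, an inhibitor of PI3 kinase (8.48).

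Among single intervals, the strongest mi8 peaks absent from OE lay 12.2 kb from Emp1 (chromosome 6, 135350136 to 135350563, −log10 q 68.8), within Gcnt1 (chromosome 19, 17339610 to 17339903, 67.9), 17.7 kb from Coq2 (65.3), 0.419 kb from Rnase6 (chromosome 14, 51132497 to 51132773, 63.9) and within 1110051M20Rik (62.4). The strongest OE peaks absent from mi8 lay 82.8 kb from Tox3 (chromosome 8, 90431689 to 90431894, 44.5), within Zbtb20, a zinc finger repressor (chromosome 16, 42897751 to 42898006, 34.0), on chromosome X with no gene within 100 kb (163386328 to 163386675, 32.1), 4.95 kb from Tnfrsf23 (31.5) and within Pter (31.4).

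Gene groups did not share the difference evenly, but the random lists were matched on regions per gene and not on peak strength. Of mi8 peaks, 85.5% with a −log10 q under 5 and 0.393% at 40 or above were absent from OE. A list can therefore lie outside through the strength of its peaks alone. Near all genes, 61685 regions were in mi8 alone and 4471 in OE alone, a net share of −35.9%. Granulocyte and mast cell markers had 58 of 103 regions in mi8 alone and 1 in OE alone (net −55.3%, percentile 0.07), with Gata2 at 8 of 11. Interferon-stimulated genes, the antiviral effectors and sensors, had 73 of 153 in mi8 alone and 0 in OE alone (−47.7%, percentile 0.51), with Cmpk2 at 7 of 8. Developmental Polycomb targets, such as Lhx2 with 10 of 16, had 57 of 107 in mi8 alone (−49.5%, percentile 0.47), but with equal numbers of peaks per list their net share was 9.68% and inside the random range.

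Glycolysis and HIF genes had 48 of 385 regions in OE alone and 96 in mi8 alone (net −12.5%, percentile 100). Hif1a supplied 25 of the OE-only regions, Egln3, the HIF prolyl hydroxylase, 12 and the glucose transporter Slc2a1 5, so most came from few genes. Without Hif1a the net share was −20.7% and still outside, but a list without all of these genes was not examined. With equal numbers of peaks per list the counts turned to 82 in OE alone and 30 in mi8 alone (net 16.3%, percentile 99.99). Cell cycle genes had 13 regions in OE alone and 51 in mi8 alone (−19.9%, percentile 99.9), 8 of the 13 at Cdkn1a, the cell cycle inhibitor p21, without which the net share was −25.1% and still outside. With equal numbers they had 32 in OE alone and 18 in mi8 alone (8.86%, percentile 98.8). Costimulation and maturation genes had 17 and 101 (−26.2%, percentile 98.9), 12 of the 17 at Cd274, the inhibitory ligand PD-L1; without Cd274 the net share was −31.9% and no longer outside, and with equal numbers it was 1.19% (36 and 33, percentile 89.3) and no longer outside either. The remaining lists lay inside the central 95%: PRC1.6 and Pcgf paralogs (net −33.9%), germline genes (−37.7%), antigen presentation (−37.8%), cytokines and chemokines (−40.4%, but −16.1% and outside, at percentile 0.505, with equal numbers), NF-kB and Toll-like receptor signalling (−32.1%), dendritic cell lineage factors (−34.4%), oxidative phosphorylation (−37.1%), ubiquitous promoters (−36.3%), and markers of macrophages (−42.7%), lymphoid and plasmacytoid cells (−41.8%), erythroid cells and megakaryocytes (−38.5%) and stroma (−38.5%).

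The knockdown was compared with LMP8 to see which sites accompany less Pcgf6. Fn1, the gene of the matrix protein fibronectin, stood out: its body (chromosome 1, 71585473 to 71653280) held 56 peaks in HP109 against 3 in LMP8, 3 in mi8 and 1 in OE. Exons are not annotated here, so whether the peaks inside Fn1, or those inside Hif1a, fall on exons, as reads from cDNA or RNA would, was not examined. Ldha, which makes lactate dehydrogenase (−log10 q 20.3), Siglech, a plasmacytoid dendritic cell receptor (12.7), the neutrophil genes Ngp (9.80) and Elane (5.47), and Cd209a, a dendritic cell lectin (2.38), had an end peak in HP109 and none in LMP8. At Ldha and Siglech OE and mi8 had an end peak too, so LMP8 alone lacked it, Ngp had one in mi8, and Elane and Cd209a had one in HP109 alone. Interferon-stimulated genes ran the other way, with 17 of 134 regions in LMP8 alone and 11 in HP109 alone. In all, 40683 HP109 peaks (23.9%, interval 23.7 to 24.1) were absent from LMP8, and 11337 LMP8 peaks (8.06%, interval 7.91 to 8.20) were absent from HP109. The HP109-only peaks were the more numerous on 21 of 21 chromosomes, as those of the longer list were between the 2 controls.

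In the fixed lists, 13 genes had an end peak in HP109 and none in LMP8, and none had the reverse. The others were Hoxc10 (6.63), Pdgfra (6.42), Cd79b (4.77), Ywhaz (4.19), Cd70 (3.89), Cd3g (3.78), Itga2b (3.33) and Hba-a1 (3.07), and 9 and 8 of the 13 kept this state with windows of 500 and 2500 bp. Over all genes, 556 had an end peak in HP109 and no counterpart in LMP8, led by Tmem269 (21.7), Acp4 (20.9), Cttn, the actin regulator cortactin (20.3), Ldha, Dhx32 (19.0), Tbx15 (18.9), Gm867 (18.9), Riiad1 (18.0), Nppb, a natriuretic peptide (17.9), and Rab39b (17.7). The reverse held for 149 genes, led by Ifi44 (11.4), H2-Q10, a class Ib MHC gene (10.3), Olfr9 (9.99), Btnl2, a butyrophilin-like inhibitor of T cells (8.68), Rxfp1 (8.23), Gm2137, Hopx and the histone variant gene Macroh2a2 (7.65 each), and Creb3l4 (7.24). Of the 10 genes named for HP109, each had an end peak in mi8 too, and all but Dhx32, Riiad1 and Nppb had one in OE.

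The strongest HP109 intervals absent from LMP8 lay within Zfp804b (chromosome 5, 7277193 to 7277357, −log10 q 48.0), Utp20 (46.3), Cd86, a costimulatory ligand for T cells (chromosome 16, 36623027 to 36623414, 39.6), Tenm4 (39.1) and Ccdc30 (37.0). Each of these 5 intervals also had a peak in OE and in mi8, so LMP8 alone lacked one. For the Cd86 interval the values were 32.1 in OE and 21.8 in mi8. The strongest LMP8 intervals absent from HP109 lay within Ndst1 (16.1), 17.8 kb from S100a6 (16.1), 5.65 kb from Il4ra, the interleukin 4 receptor (16.01), on chromosome 13 with no gene within 100 kb (15.9) and within Rufy3 (14.97).

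Near all genes the net share of HP109 over LMP8 was 16.7%, and 16 of the 18 lists lay inside the range of random lists. Interferon-stimulated genes lay below it (net −4.48%, random median 16.7%, percentile 0); without Ifit2, with 3 regions in LMP8 alone and 0 in HP109 alone, the net share was −2.40% and still outside. Cytokines and chemokines had 43 regions in HP109 alone and 21 in LMP8 alone (7.86%, percentile 0.62); without Ccl2, with 1 and 6, the net share was 10.5% and no longer outside, and with equal numbers of peaks it was −2.70% (percentile 16.1). The others were PRC1.6 and Pcgf paralogs (12.9%), germline genes (17.2%), antigen presentation (9.27%), costimulation and maturation (12.6%), NF-kB and Toll-like receptor signalling (12.5%), dendritic cell lineage factors (16.5%), glycolysis and HIF (10.9%), oxidative phosphorylation (19.3%), cell cycle (19.0%), developmental Polycomb targets (20.5%), ubiquitous promoters (17.8%), and markers of macrophages (11.2%), granulocytes and mast cells (14.9%, but −12.3% and outside, at percentile 1.76, with equal numbers), lymphoid and plasmacytoid cells (19.9%), erythroid cells and megakaryocytes (25%) and stroma (18.0%). Over the comparisons of each Pcgf6 vector with its control, 8 of 36 percentiles lay outside the central 95%, where 1.8 would by chance: 6 of 18 for OE and 2 of 18 for HP109. Between the 2 controls, with no Pcgf6 vector in either, 3 of 18 did, so the 2 of 18 for HP109 are no more than that background. With equal numbers of peaks per list, HP109 and LMP8 were nearly balanced, with 15117 and 14725 peaks absent from the other. Lists of equal length tend towards such a balance whatever they hold, so it is no result about the vectors.

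**Figure D2:**
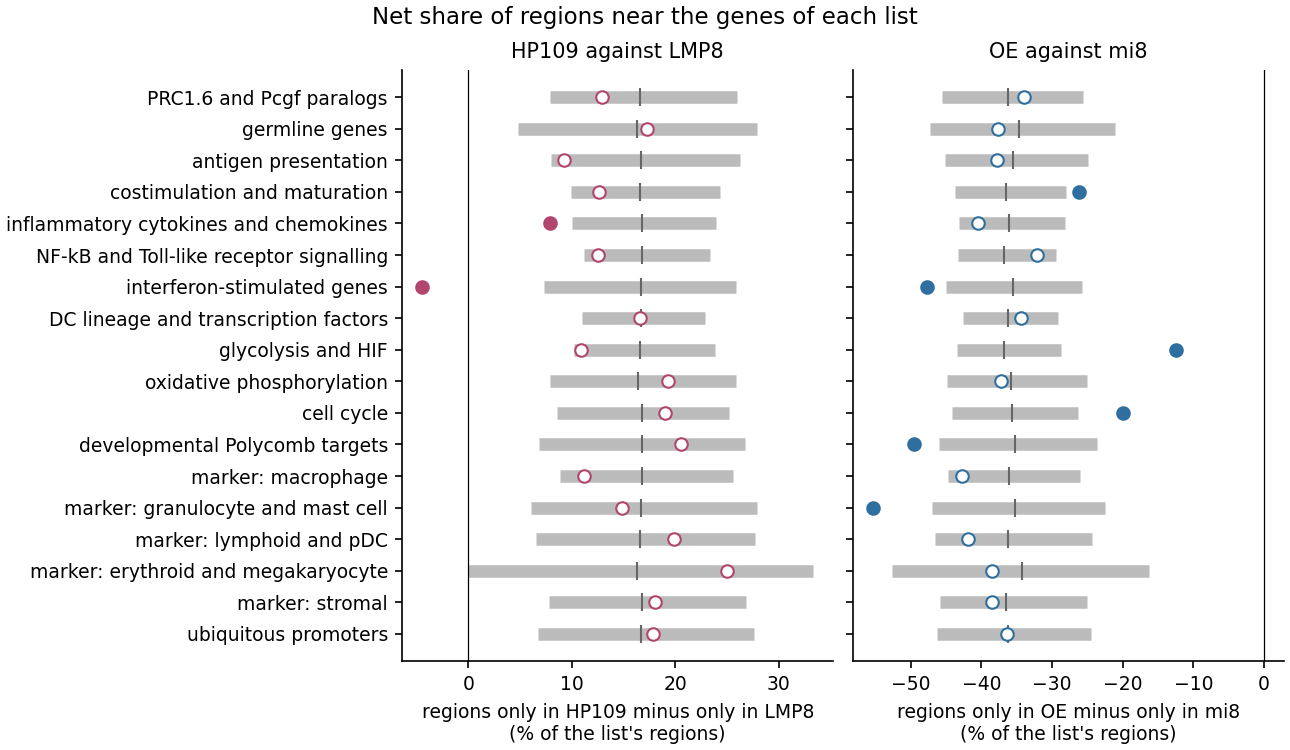
Net share of regions (percent, first list alone minus second alone) near the genes of each fixed list for HP109 against LMP8 and OE against mi8. Grey bars span the central 95% of 10000 random gene lists and ticks their median; filled points lie outside, among them interferon-stimulated genes in both comparisons and glycolysis and HIF genes in OE against mi8.

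The control vectors were compared with each other as a background. The germline gene Mov10l1 (3.63) had an end peak in LMP8 and none in mi8, while Siglech (16.6), Ccl5 (11.3), Ngp (10.7), Ldha (5.76) and Ccr7 (4.76) had one in mi8 and none in LMP8. Interferon-stimulated genes had a net share of −18.8% for LMP8 over mi8, beside −18.96% near all genes and a percentile of 50.6. Lymphoid and plasmacytoid markers (−29.7%, percentile 0.99), dendritic cell lineage factors (−12.1%, percentile 99.6) and macrophage markers (−10.6%, percentile 98.9) lay outside the random range. Between the controls 42528 mi8 peaks (24.9%) and 8409 LMP8 peaks (5.98%) were absent from the other list, so the HP109 and LMP8 lists, with a Jaccard index of 0.690, were as alike as the controls were, at 0.688. OE and mi8 were further apart, at 0.568. Among the strongest LMP8 intervals absent from mi8 were those at Rars2 (17.0), Slc39a6 (13.6), Adipor1 (13.6) and Zdhhc13 (12.5), and the strongest mi8 intervals absent from LMP8 lay at Mctp1 (39.4), Mettl15 (35.9), Specc1l (33.3), Bcl2l14 (33.0) and Cd36, a scavenger receptor (32.1).

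**Figure D3:**
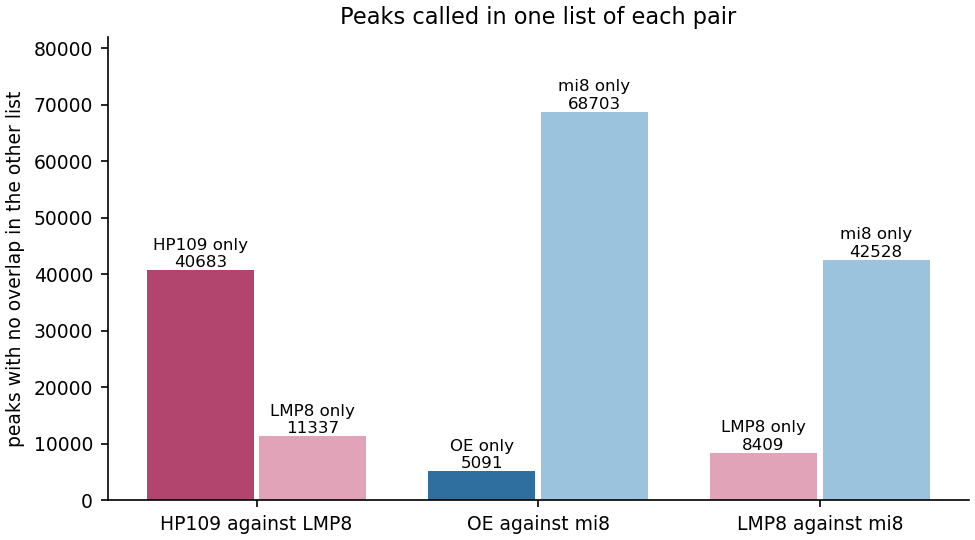
Number of peaks of each list with no overlap in the other list of its pair, for HP109 against LMP8, OE against mi8 and the controls LMP8 and mi8 against each other. The 68703 mi8 peaks absent from OE and the 40683 HP109 peaks absent from LMP8 stand beside 42528 mi8 peaks absent from LMP8.

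Peaks absent from the other list were mainly weak ones. Of mi8 peaks with a −log10 q under 5, 85.5% were absent from OE, against 39.0% from 10 to 20 and 0.393% at 40 or above. Of HP109 peaks, 67.1% under 5, 13.3% from 10 to 20 and 0.00513% at 40 or above were absent from LMP8. By location, 12.3% of all mi8 summits lay within 1000 bp of a gene end and 8.48% of those absent from OE did; for HP109 the shares were 12.8% and 7.26%. For LMP8 they were 14.2% and 12.1% of those absent from HP109, and for OE 15.5% and 8.21% of those absent from mi8. Matched on pileup, absence was more frequent away from gene ends than at them in mi8 (29.3% against 27.6%), HP109 (18.4% against 13.5%) and OE (4.05% against 2.43%), and less frequent in LMP8 (5.92% against 6.88%).

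**Figure D4:**
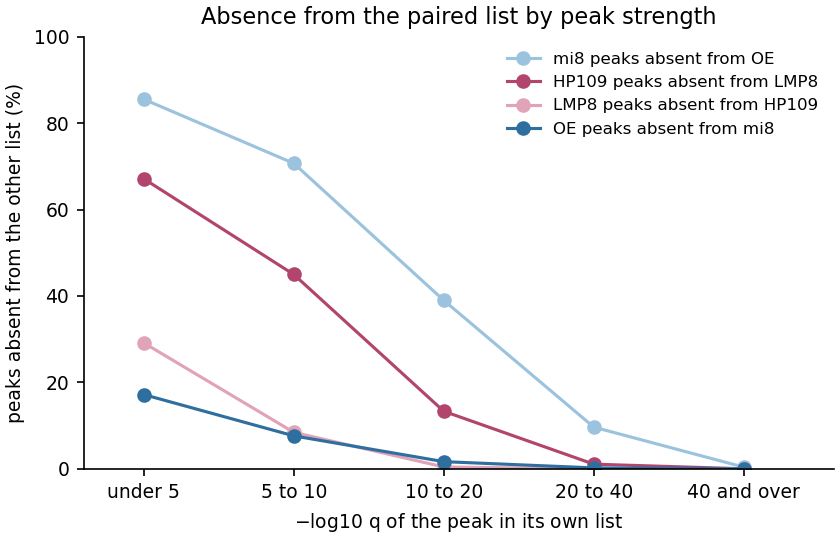
Share of peaks absent from the other list (percent) by the −log10 q of the peak in its own list, for mi8 against OE, HP109 against LMP8 and the reverse directions. In every curve the share is highest for the weakest peaks, from 85.5% in mi8 to 17.2% in OE.

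The opposed question was whether regions that accompany the knockdown are those missing with overexpression. Gene ends with a peak in HP109 and mi8 and no counterpart in LMP8 or OE numbered 259, among them Fbxl17, Ano7, Papln, Sparcl1, Nppb, Asic4, Dhx32, Scube2 and Siah3. In the reverse state, Ggn, a germ cell gene, was the single gene found, and its peak overlapped one of an absent list outside the window. Over all regions, 15313 were in HP109 and mi8 alone and 175 in LMP8 and OE alone, beside 4871 in LMP8 and mi8 alone and 1691 in HP109 and OE alone. HP109 and mi8 are the longest lists and LMP8 and OE the shortest. The counts of regions and of gene ends therefore cannot show opposed action, because list length alone favours the first state. Of 20834 mi8 regions present in HP109 and absent from LMP8, 73.5% were absent from OE. Of 5625 mi8 regions present in LMP8 and absent from HP109, 86.3% were absent from OE after matching on mi8 −log10 q, so the difference was −12.8 points and was positive in 0 of 20 chromosomes. Among all mi8 regions, 40.1% were absent from OE.

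Some genes held many absent peaks inside their span, a ranking chosen after the data were examined. For OE over mi8, Hif1a had 18 of 30 OE peaks absent from mi8 (60.0%, against 4.57% of all OE peaks) and Slc7a2, an arginine transporter, 18 of 34, with 15 peaks in mi8 and 12 each in HP109 and LMP8. For mi8 over OE, Atp2b1, a calcium pump, had 83 of 103 and Cd44, a hyaluronan receptor, 63 of 80 mi8 peaks absent from OE, with 20 OE peaks in each gene. For HP109 over LMP8, Fn1 had 53 of 56 HP109 peaks absent from LMP8 (94.6%), Plxdc2 55 of 109 and Sarnp 27 of 34. For LMP8 over HP109, Osbpl8 and Atp2b1 ranked highest, although HP109 had more peaks in them than LMP8 (75 against 68 and 66 against 65). Behind them, Ifi207, of an interferon-inducible family, had 15 of 19 LMP8 peaks absent from HP109, with 4 peaks in HP109, 3 in OE and 15 in mi8. Most of these peaks were weak: with a −log10 q of at least 10, Fn1 had 8 peaks in HP109 and 1 in each other list, and Hif1a had 9 in OE, 6 in mi8, 7 in HP109 and 3 in LMP8. At that cut Slc7a2 had 7 peaks in OE and 7 in mi8. Ifi207 had 2 in LMP8 and 2 in HP109, so neither gene kept its higher count. Atp2b1 (25 in mi8, 11 in OE), Cd44 (20 and 13), Plxdc2 (43 in HP109, 18 in LMP8) and Sarnp (5 and 1) kept theirs. The counts at this cut were not set against the lengths of the whole lists, so they do not show an excess beyond the expected share.

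**Figure D5:**
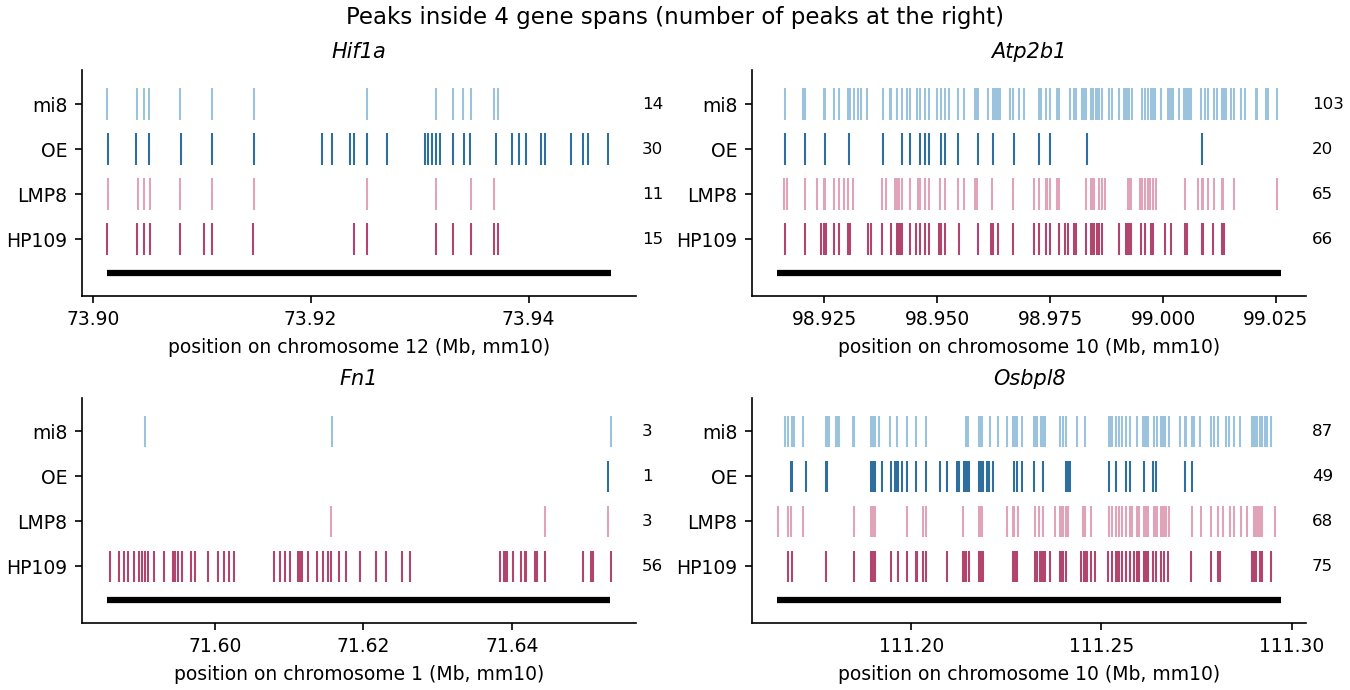
Position (Mb, mm10) of every peak inside Hif1a, Atp2b1, Fn1 and Osbpl8, the first gene of each direction by absent peaks, in the 4 lists, with the number of peaks at the right and the gene as a black bar. Fn1 holds 56 peaks in HP109 and at most 3 in any other list, and Hif1a holds 30 in OE and at most 15 in any other list. Osbpl8, first for LMP8 over HP109, holds 68 peaks in LMP8 and 75 in HP109.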

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

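Among the tests given here, the depth ratios of both Pcgf6 vectors against their controls were chosen after the peak counts had been seen. The mitochondrial chromosome was left out of every comparison, and each list nevertheless holds peaks there that pass the authors' threshold. The highest fold over the input was 8.12 in HP109 (2 peaks), 5.39 in OE (3 peaks), 4.67 in mi8 (4 peaks) and 3.89 in LMP8 (15 peaks).

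The shorter OE list, with 68703 mi8 peaks missing, goes with equal depth, since the ratio of recovered depths was 0.998. A lower enrichment of the OE libraries at all sites would need a drop of at least 0.3 (log2) at gene ends of ubiquitous genes, and the median there was −0.01 (−0.0148; bootstrap interval −0.10 to 0.06). That reading is later than the value. The bound fixed beforehand asked for a median of 0 or more, which was narrowly missed. Strong sites may saturate after duplicate removal, so the ubiquitous genes cannot exclude a lower enrichment at weaker sites. A near-even loss over locations stays open, since mi8 peaks away from gene ends were absent 1.71 points more often than those at gene ends, but it was not fully even: this held in 20 of 20 chromosomes, and over shared regions the median log2 ratio of pileups was −0.37 away from gene ends and −0.21 at them. An effect of Pcgf6 also stays open, because the −12.8 points of the opposed regions, which met the bound set beforehand against a mirrored effect, rest on regions gained in HP109, where signal was higher at ubiquitous genes too (0.65). This verdict was changed to open after the −12.8 points had been seen.

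The longer HP109 list also goes with equal depth, at a ratio of 0.992. A higher enrichment of the HP109 libraries at all sites is a candidate explanation. The median log2 ratio of summit pileups at gene ends of ubiquitous genes was 0.652 (interval 0.54 to 0.71), with 17 of 17 genes higher. A ratio cannot tell higher signal in HP109 from lower signal in LMP8. HP109 and mi8 had a Jaccard index of 0.709, above the 0.690 of HP109 and LMP8, so a weaker LMP8 list stays open as well. An even gain over locations also stays open at 4.90 points, just under its bound of 5 and positive in 20 of 20 chromosomes. A rise that follows from less Pcgf6 was not separated from this, and regions gained in HP109 are for that reason no clean marker of Pcgf6 loss.

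The lists of the control vectors differ about as much as HP109 and LMP8. Depth was 1.37 times as high in mi8. After thinning mi8 to the LMP8 depth the mi8-only peaks were still 4.07 times the LMP8-only peaks. Thinning lowered the summit pileups of peaks already called and called no peaks anew. It may keep too many weak peaks and cannot settle how far depth is the cause. The vector and the culture go together here, and both stay open too.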

How the results depend on the processing

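The thinned lists and the exchanged controls were chosen after seeing the data. No paired analysis was possible because there is 1 pooled list per vector. Every alternative left the longer list of each pair with more peaks of its own, nearly balanced for HP109 against thinned mi8. Of 46 counts or shares that answer a comparison, 23 stayed within their limits and 23 moved. With −log10 q of at least 5, LMP8-only peaks were 6347 against HP109 and 5019 against mi8, and the opposed difference was −14.6 points. With at least 10, LMP8-only peaks were 2691 and 1717, OE-only 2987, mi8-only against OE 39390, and the opposed difference −18.9. With equal numbers, HP109-only peaks were 15117, OE-only 16862, mi8-only 21626 against OE and 14871 against LMP8, and the opposed difference −15.5. Shorter lists lose their weak peaks by construction, and lists of equal length tend towards balance. With at least 10 in 1 list and none in the other, HP109-only peaks were 4920 and LMP8-only 137, OE-only 450 and mi8-only 17150, and LMP8-only 52 and mi8-only 4441 between the controls. With thinned mi8 as the control, HP109-only peaks were 24099 and control-only 24032; with LMP8 as the control of thinned OE, 11122 and 43857. Counts of gene ends stayed within 1.5 times in 12 of 12 alternatives, and the log2 ratios of peak counts moved in 20 and stayed in 1. Net shares of gene lists changed no sign and no call with a 20 kb limit. With equal numbers of peaks, which put the net share near all genes at 0.792% for HP109 against LMP8 and −3.98% for OE against mi8, 14 of 18 lists changed sign in the former and 5 of 18 in the latter. Of lists outside the random range, those that changed sign were glycolysis and HIF (16.3%), cell cycle (8.86%), costimulation and maturation (1.19%) and developmental Polycomb targets (9.68%) in OE against mi8, and cytokines and chemokines (−2.70%) in HP109 against LMP8; the last 3 were then inside. Cytokines and chemokines in OE against mi8 (−16.1%) and granulocyte and mast cell markers in HP109 against LMP8 (−12.3%) were outside with equal numbers alone. Developmental Polycomb targets also changed sides of the random median; the cause was not tested. Motifs and exon classes were not run. Thinning mi8 to the LMP8 depth left 166018 of its 170976 peaks.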

Other observations

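Tests chosen after the results were seen are the one on regions shared by the controls alone, the percentiles of pileup ratios and the gene ends named from the controls. Interferon-stimulated genes lacked more regions with either Pcgf6 vector than other genes did. Of their 162 regions, 11 (6.79%) were in both control lists and in neither Pcgf6 vector, at Ifit2, Oas1a, Oas3, Rsad2, Irf7, Irf9, Ifih1 and Cmpk2, genes of viral RNA sensing and antiviral defence. Near all genes the share was 2.46%. Granulocyte and mast cell markers had 7 of 116 (6.03%, percentile 98.1), including S100a9, Ctsg and Kit, while cell cycle genes had 1 of 228 and ubiquitous genes 0 of 173. At gene ends, 84 genes had a peak in both controls and no counterpart in either vector, led by Ifi44 (−log10 q 11.4 in LMP8 and 33.3 in mi8), H2-Q10 (10.3 and 19.3), Btnl2 (8.68 and 7.53) and Creb3l4 (7.24 and 13.3), with Ly6c1, a monocyte marker, further down (6.29 and 17.7).

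The recovered summit pileups of OE and mi8, whose depths were equal, give a second view that leaves out genes with no OE end peak. Interferon-stimulated genes had a median log2 ratio of −0.55 (18 of 22 lower, random median −0.18, percentile 0), with pileups of 14 in OE and 40 in mi8 at Ddx58, the RIG-I sensor, 22 and 60 at Oas2 and 26 and 67 at Rsad2, the antiviral enzyme viperin. Cytokines and chemokines had −0.44 (15 of 17 lower, percentile 0.555), with 30 and 61 at Ptgs2, which makes prostaglandins. Lymphoid and plasmacytoid markers had −0.63 (7 of 9 lower, percentile 1.26). Macrophage markers had −0.40, inside the random range, with 22 and 71 at the complement gene C1qb. Oxidative phosphorylation genes had 0.00 (percentile 99.1), above the random range. Of the 6 lists outside by net share of regions, interferon-stimulated genes alone were outside here. Glycolysis and HIF genes had −0.08 (percentile 32.3), cell cycle genes −0.05 (74.3), granulocyte and mast cell markers −0.38 (40.7) and developmental Polycomb targets −0.34 (84.1). Costimulation and maturation genes, high by regions, had −0.46 (16 of 17 lower, percentile 6.70), toward the other side. For HP109 over LMP8 every list was higher, from 0.42 to 0.65, and 0 of 18 lay outside.

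A lower interferon state in cells with either Pcgf6 vector is a hypothesis for the regions shared by the controls alone. The share of 6.79% lay at percentile 99.8 of random gene lists, but the list was taken up because its net share was low in both comparisons, so this restates what prompted the hypothesis and does not test it. Summit pileups at their gene ends were higher in HP109 than in LMP8 for 19 of 22 genes, with a median log2 ratio of 0.44. This was inside the range of random lists (0.43 to 0.64) but near its lower bound, at percentile 3.07. The 2 vectors are expected to move Pcgf6 in opposite directions, so a shared difference may stem from the vectors or cultures rather than from the level of Pcgf6, and nothing here separates these.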
